A study of Mus musculus with 8 samples.

How the data were processed

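Oocytes were grown from embryonic stem cells in steps that the labels' protocols describe. Primordial germ cell-like cells made from the stem cells were put together with somatic cells of female fetal gonads from embryonic day 12.5, at 5000 germ cells to 75000 somatic cells, into aggregates called reconstituted ovaries. These were kept for 21 days in differentiation culture and oocytes were collected on day 11 of growth culture as GV oocytes, or after a further 16 hours of maturation as MII oocytes. Cumulus cells were removed with a glass capillary at GV or with hyaluronidase at MII, MII oocytes were picked by their first polar body, and oocytes with the fluorescent Stella (Dppa3) reporter that the stem cells carry were collected. Per the labels, 31 to 158 oocytes at GV or 35 to 58 at MII were pooled per library, and stranded libraries of polyadenylated RNA were made with 13 cycles of PCR and read as single reads of 75 bases. Groups were taken from the titles of the samples, which give the line and the stage, with 2 libraries in each of 4 groups.

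The deposited values are raw counts of reads per gene in 1 table of 55385 genes, made by the authors from trimmed and aligned reads. Per the submitters' processing notes, Trimmomatic 0.38 was used for trimming, HISAT2 2.1.0 for alignment, featureCounts 2.0.0 for counting and mm10 as the genome build. DESeq2 1.30.1 is named in the same notes, and the counts show no normalization, being whole numbers with different totals per library. The strand used in counting, the treatment of reads with several matches and the annotation release are not given in the sources used here. This affects antisense genes, whose reads cannot be told from those of the gene on the other strand if counting ignored strand, and genes with near-identical copies, such as ribosomal protein genes and their pseudogenes, which may lose or share reads. Gene names, coordinates and transcript sequences were taken from GENCODE M21 on GRCm38, the assembly that mm10 names. By identifier without its version, 55144 genes matched and 241 did not, and the latter held 0.0033% of reads.

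Counts were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood method (estimateDisp, glmQLFit and glmQLFTest at default settings) with trimmed mean of M-values (TMM) factors. All 8 libraries entered 1 fit with a coefficient per group, so that all comparisons shared 1 estimate of the spread with 4 residual degrees of freedom. Genes were kept by filterByExpr with the groups, at its minimum count of 10, which left 14929. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The common biological coefficient of variation was 0.243. Standard errors were taken as the absolute log2 fold change over the square root of the F statistic, an approximation under the quasi-likelihood model. The comparisons were sex-converted against native at GV and at MII, MII against GV in each line, and the line by stage interaction, given as the change in the sex-converted line minus that in the native line. CPM values are counts scaled by library total and TMM, whose factors were 1.33 to 1.43 at GV and 0.714 to 0.733 at MII. TMM assumes that the bulk of genes balances out, so a change from GV to MII is a change relative to other mRNAs, and a change in the total mRNA of an oocyte is not measured.

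The 25 gene lists were fixed before the data were examined. They cover oocyte identity, maternal mRNAs recruited for translation, the meiotic cell cycle, mRNA decay, cytosolic ribosomal proteins, the mitochondrial ribosome, the respiratory chain, mitochondrially encoded genes, the proteasome, zinc finger genes, granulosa and cumulus markers, stromal and theca markers, endothelial and blood markers, pluripotency and germ cell genes, testis genes, Y-linked genes, X inactivation centre and escape genes, imprinted genes, DNA methylation and chromatin genes, piRNA and siRNA genes, p53 and DNA damage genes, stress genes, genes of the 2-cell embryo, sterol synthesis and glycolysis. Each list of at least 3 tested genes was tested by camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry, which asks whether a list's genes move one way and does not compare them with other genes. Chromosomes 1 to 19 and X were tested in the same way. Counts of called members were also made with p adjusted over the list alone.

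The genes named follow a rule set before the data were examined. It takes the 12 called genes with the largest log2 fold change in each direction of a comparison at a mean of at least 10 CPM in the higher group, leaving out predicted models and clones, and 6 in each direction for the interaction. It adds up to 3 called members of each list in each direction, or the 2 most abundant members where none was called. It always includes Xist, Ddx3y, Eif2s3y, Kdm5d, Uty, Zp3, Gdf9, Bmp15, Nlrp5, Dppa3, Mos, Btg4 and Ccnb1, and the 10 leading genes called in the same direction in both line comparisons. Some genes that the rule takes are left out of the text, and genes outside it are marked as chosen after their values were seen.

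Where a group had 0 reads, the fold is a bound against a floor of 3 reads over the group, and where it had 1 to 3 reads the ratio of counts is given with an exact counting interval at 95%. Such intervals cover counting error only, since PCR copies are not independent molecules. A floor leaves out the counting error of the group with reads. A fold given as at least a value is thus a fold against the floor and not a limit at 95%. The same rule was used with a library left out, where the floor or the few reads stand against the total of the library that is left. In the library with the lowest total, 3 reads stand for 0.291 CPM before TMM scaling. Replicates within a group differed by more than counting noise, with a chi-square per degree of freedom of 10.2 to 41.3, and no library was counted as a copy of another. The labels do not say which oocyte cultures the 2 libraries of a group came from beyond calling them biological duplicates. The p-values rest on the spread between libraries of a group, pooled over both lines and both stages. Whether this is a spread between cultures is not known. Each line is a single line, so the p-values do not measure a spread between lines of a kind.

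The scripts were tested on simulated counts with the means and library totals of the real data and 200 genes changed by known folds. These 200 genes were drawn from those with a mean of 10 CPM or more, so recovery at lower levels was not tested. For the line comparison at GV, 38.8% of seeded 2-fold, 98.5% of 4-fold and 100% of 8-fold changes were called, and 17 of 14729 unchanged genes. For the line comparison at MII the shares were 32.8%, 98.5% and 100%, with 4 unchanged genes called. For maturation in the native line they were 26.9%, 100% and 100%, with 12 unchanged genes called. None of 100 random sets reached an unadjusted p under 0.05 in these 3 simulations. The simulated genes were drawn independently, so this does not show how camera behaves with correlated genes.

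Alternatives set before the data were examined were DESeq2 1.42.0, relative log expression (RLE) factors, library totals as the only scaling, no filter on low counts, a minimum mean of 50 reads, robust dispersion, totals without mitochondrial and the 20 most abundant genes, libraries thinned to the smallest total, the replicate number as a block, only the 4 libraries compared, an adjusted p under 0.01, a 2-fold minimum and leaving out each library in turn. Removal of the GC trend of each library within its stage, a covariate for a split of the GV libraries and a looser threshold for the line differences at both stages were added after the data were seen. Transcript GC content came from the longest transcript of each gene, and its trend was removed by loess with a span of 0.3 on log ratios with a prior count of 2. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.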

Results

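The series measured polyadenylated RNA in pools of mouse oocytes that had been grown in culture from embryonic stem cells. The oocytes came from 2 XX stem cell lines. In one, named sex-converted in the labels, the XX cells had been derived from male cells, and the other was XX from the start and is called native here. Oocytes were collected either at the germinal vesicle stage (GV, grown oocytes arrested in prophase of the first meiotic division) or at metaphase II (MII, matured eggs arrested before fertilisation). Each combination of line and stage held 2 libraries, which the labels describe as biological duplicates. Total counts were 11741295 and 14999003 reads in sex-converted GV oocytes and 13541580 and 10306471 reads in native GV oocytes. They were 12479197 and 14389689 reads in sex-converted MII oocytes and 14690428 and 11894026 reads in native MII oocytes. The design gives 3 questions, which are how oocytes of the lines differed at each stage, how each line changed in maturation, and whether that change differed between the lines. Stage was the main difference between libraries, as the first principal component held 85.5% of the variance. Correlations of log CPM, the counts scaled to a common library total, were 0.961 to 0.981 within a stage and 0.759 to 0.796 between stages.

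GV oocytes of the sex-converted and native lines differed in 2 genes of the 14929 tested. Parp8, a member of the poly(ADP-ribose) polymerase family, was at 15.1 ± 1.0 CPM in the sex-converted line and at 0.992 ± 0.408 CPM in the native line (SD, n = 2 each). Gm14820, an antisense gene of the X chromosome, was at 0.794 ± 0.227 CPM in the sex-converted line and at 91.0 ± 2.79 CPM in the native line (SD, n = 2 each). The log2 fold changes of sex-converted over native were 3.89 for Parp8 (SE 0.422, adjusted p = 0.013) and -6.84 for Gm14820 (SE 0.471, adjusted p = 0.000259) in edgeR's quasi-likelihood test. Each library of one line lay on the same side of each library of the other. With 0.1 added to each CPM, pairwise log2 ratios were 3.39 to 4.31 for Parp8 and -6.40 to -6.99 for Gm14820. Parp8 (ENSMUSG00000021725.9) lies on the minus strand of chromosome 13 from 116854820 to 117025537 in GRCm38. Gm14820 (ENSMUSG00000087193.7) lies on the plus strand of chromosome X from 8042943 to 8074619 and overlaps the histone methyltransferase gene Suv39h1 on the other strand. It fell outside the rule for named genes and was chosen after its values were seen. Suv39h1 itself was also outside the rule and chosen after the values were seen. It had 60 and 40 reads in the sex-converted libraries and 51 and 59 in the native ones. Its log2 fold change was -0.34 (SE 0.481). Since the counting strand is not given in the sources used here, reads of Gm14820 and Suv39h1 cannot be fully told apart where they overlap. At an unadjusted p under 0.05 there were 319 genes, and DESeq2 called 2 higher and 1 lower, the additional one being the predicted gene Gm1821. Gm1821 was likewise named after its values were seen, and its log2 fold change was 1.63 without sex-converted GV replicate 2 against 2.60 with it. The call of Parp8 was lost without native GV replicate 2 (log2 fold change 3.54, adjusted p = 0.0857) and when only the 4 GV libraries were fitted (adjusted p = 0.1).

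**Figure D1:**
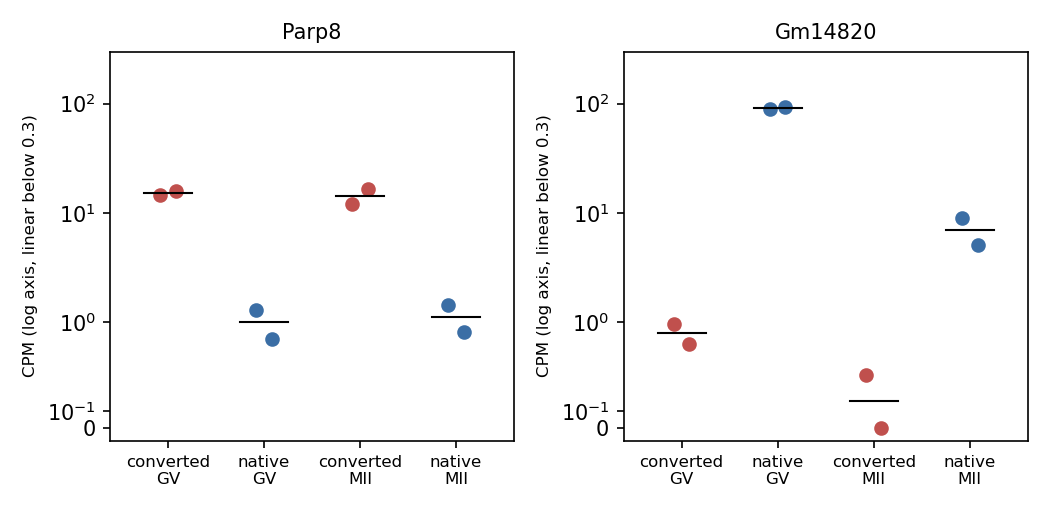
CPM of Parp8 and Gm14820 in each of the 8 libraries, with 1 point per library and a line at the mean of each group (n = 2), on an axis that is logarithmic above 0.3 CPM and linear below it. Parp8 was at 12 to 16.5 CPM in the sex-converted libraries and at 0.704 to 1.43 CPM in the native ones, and Gm14820 was at 0.954 CPM or less in the sex-converted libraries and at 5.09 to 92.9 CPM in the native ones.

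Genes of oocyte identity were at similar levels in GV oocytes of both lines, and 0 of 39 were called. Gdf9, a growth factor that oocytes secrete, was at 4032 ± 340 CPM in the sex-converted line and 4319 ± 58.8 CPM in the native line (SD, n = 2 each), with a log2 fold change of -0.10 (95% interval -0.377 to 0.179). Its partner Bmp15 had a log2 fold change of -0.15 (95% interval -0.685 to 0.379). Zp3, a protein of the zona pellucida, had -0.021 (95% interval -0.572 to 0.529). Nlrp5 and Dppa3, maternal factors needed by the early embryo, had -0.047 and -0.20, with 95% intervals of -0.431 to 0.336 and -0.623 to 0.225. Among maternal mRNAs recruited for translation in maturation, 0 of 26 were called, and the kinase gene Mos, the deadenylation adaptor gene Btg4 and the cyclin gene Ccnb1 had log2 fold changes of -0.0020, 0.10 and 0.17. Among genes with a mean of 10 CPM or more, 7683 in all, the median absolute log2 fold change was 0.121 at GV, and the 95% interval lay within a 2-fold change either way for 86% of them. The test could therefore have missed smaller differences. In simulated data for this comparison it found 38.8% of seeded 2-fold changes and 98.5% of seeded 4-fold changes. The seeded genes also had a mean of 10 CPM or more, so recovery of genes with fewer reads was not tested.

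None of the 24 gene lists with at least 3 tested members was called at GV by camera, with 6 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0595. Camera with an estimated correlation and fry also called 0, but 1 list was called with RLE factors and 1 with the replicate number as a block. With a GV library left out, 1 list was called without sex-converted replicate 1, 3 without sex-converted replicate 2, 3 without native replicate 1 and 5 without native replicate 2. No gene was called when adjusted over the list alone. That smallest value belonged to genes of the 2-cell embryo, of which 6 were tested, with a median log2 fold change of 0.33 at GV. Mitochondrially encoded genes stood apart in the GV libraries in a way that crossed the lines, with a median of 57.6 CPM in sex-converted replicate 1 and 58.4 CPM in native replicate 2 but 173 CPM in sex-converted replicate 2 and 211 CPM in native replicate 1.

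The Y-linked genes of the lists and Xist gave at most 83 reads in any library. Of the Y-linked genes that always entered the list of named genes, Eif2s3y and Uty had 0 reads in all 8 libraries, and Ddx3y had 1 read in native GV replicate 2 and 0 in the others. Kdm5d, the Y-linked copy of a histone demethylase gene, had 49 and 33 reads in sex-converted and 25 and 30 in native GV oocytes, and at most 2 reads in any MII library. Its X-linked copy Kdm5c, named after its values were seen, went the other way from GV to MII, though not between the lines at GV. It had 1024 and 724 reads in sex-converted and 562 and 600 in native GV oocytes, and 1047 to 1366 in the MII libraries. Both lines are XX, and the source of the Kdm5d reads is not known in either. Xist, the RNA of X inactivation, had 0 reads in sex-converted GV oocytes and 2 and 0 in native GV oocytes. At MII it had 19 and 3 reads in the sex-converted libraries and 83 and 7 in the native ones. Its log2 fold change was -1.92 (SE 1.10, adjusted p = 1 in edgeR). It became 0.54 and -2.74 without native MII replicates 1 and 2, and -3.89 and -1.07 without sex-converted MII replicates 1 and 2.

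The X chromosome as a whole did not separate the lines. The median log2 fold change of its 527 tested genes was -0.032 at GV (adjusted p = 0.987) and 0.034 at MII (adjusted p = 0.96) by camera. Of 20 chromosomes, 0 were called at either stage by camera with the preset or an estimated correlation or by fry, and 0 had an unadjusted p under 0.05. The ratio of the median level per kilobase of X-linked to autosomal genes was 0.782 ± 0.035 in sex-converted and 0.80 ± 0.12 in native GV oocytes (SD, n = 2 each). At MII it was 0.94 ± 0.057 and 0.986 ± 0.035. With 2 libraries against 2 an exact permutation test cannot reach a p under 0.05, and the ratios were not tested.

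MII oocytes of the lines differed in the same 2 genes, in the same directions as at GV. Parp8 was at 14.3 ± 3.12 CPM in the sex-converted line and 1.12 ± 0.44 CPM in the native line, and Gm14820 was at 0.164 ± 0.232 and 6.99 ± 2.68 CPM (SD, n = 2 each). The log2 fold change of Parp8 was 3.64 (SE 0.439, adjusted p = 0.0369 in edgeR). Gm14820 had 3 reads in sex-converted and 137 in native MII oocytes, a ratio of 46.9 (95% counting interval 15.7 to 230), with a fitted log2 fold change of -5.43 (SE 0.657, adjusted p = 0.0369). Oocyte genes were again close, with log2 fold changes of -0.16 for Gdf9, 0.25 for Bmp15, -0.25 for Zp3, 0.17 for Nlrp5 and 0.013 for Dppa3, and 0 of 39 of their list were called. Over genes at 10 CPM or more the median absolute log2 fold change was 0.137, and the 95% interval lay within a 2-fold change either way for 78.3%. At an unadjusted p under 0.05 there were 549 genes, and DESeq2 called 2 higher and 1 lower. Its additional call was Gm47913, a long non-coding RNA gene of chromosome 13 from 116651448 to 116663591, named after its values were seen. It had 136 reads in sex-converted and 3 in native MII oocytes, a ratio of 44.1 (95% counting interval 14.8 to 216). At GV it had 51 against 0, 14.7-fold higher in the sex-converted line against the floor of 3 reads. The exact 95% counting interval at GV had a lower limit of 11.5. With a library left out the ratio at MII was lowest without native MII replicate 2 (24.2), with a bound of 19.9 without native MII replicate 1, and the bound at GV was 6.48 to 19.2. Both edgeR calls at MII were lost without sex-converted MII replicate 1 (adjusted p = 0.068, Parp8 at 3.86), sex-converted MII replicate 2 (0.365, 3.41) or native MII replicate 1 (0.234, 4.14), with library totals as the only scaling (0.053), with a minimum mean of 50 reads (0.0732) and with the replicate number as a block (0.109 for Parp8 and 0.0858 for Gm14820). The call of Parp8 was also lost without native MII replicate 2 (3.33, adjusted p = 0.168), and that of Gm14820 when only the 4 MII libraries were fitted (adjusted p = 0.187). The ratio of Gm14820 was 21.8 without sex-converted MII replicate 2, 33.3 without native MII replicate 1 and 58.2 without native MII replicate 2, and at least 25.1 without sex-converted MII replicate 1, where 0 reads were left.

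Cytosolic ribosomal protein genes were lower as a list in sex-converted than in native MII oocytes, but 1 native library set this difference. The median log2 fold change of the 87 tested genes was -0.64 (camera adjusted p = 2.75e-10, and adjusted p = 0.989 with an estimated correlation). Of these 87 genes 0 were called, over all genes or adjusted over the list alone. Nuclear genes of the respiratory chain had a median of -0.10 over 82 genes (camera adjusted p = 0.00481, and adjusted p = 0.989 with an estimated correlation), with 0 called. Without native MII replicate 1 the ribosomal protein median was 0.25 (adjusted p = 0.396) and the respiratory chain median 0.20 (adjusted p = 0.529). Without sex-converted MII replicate 2 the respiratory chain call was also lost (median -0.087, adjusted p = 0.598). The median ribosomal protein gene was at 8.98 CPM in native MII replicate 1 and at 2.89 CPM in native MII replicate 2, beside 4.27 and 2.47 CPM in the sex-converted libraries. Markers of granulosa and cumulus cells, the somatic cells around the oocyte, had a median of 8.02 CPM in native MII replicate 1 and of 2.20, 2.41 and 1.24 CPM in the other libraries. The mesenchymal gene Vim had 175 reads in that library and 21, 67 and 15 in the others, and the granulosa gene Inha had 84 reads and 21, 29 and 0, both named after their values were seen. Not all markers followed, as the stromal list had a median of 1.34 CPM in that library and 1.45 CPM in native MII replicate 2, and the cumulus gene Has2 was lower there (4.58 CPM) than in the other MII libraries (5.79 to 6.68 CPM).

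**Figure D2:**
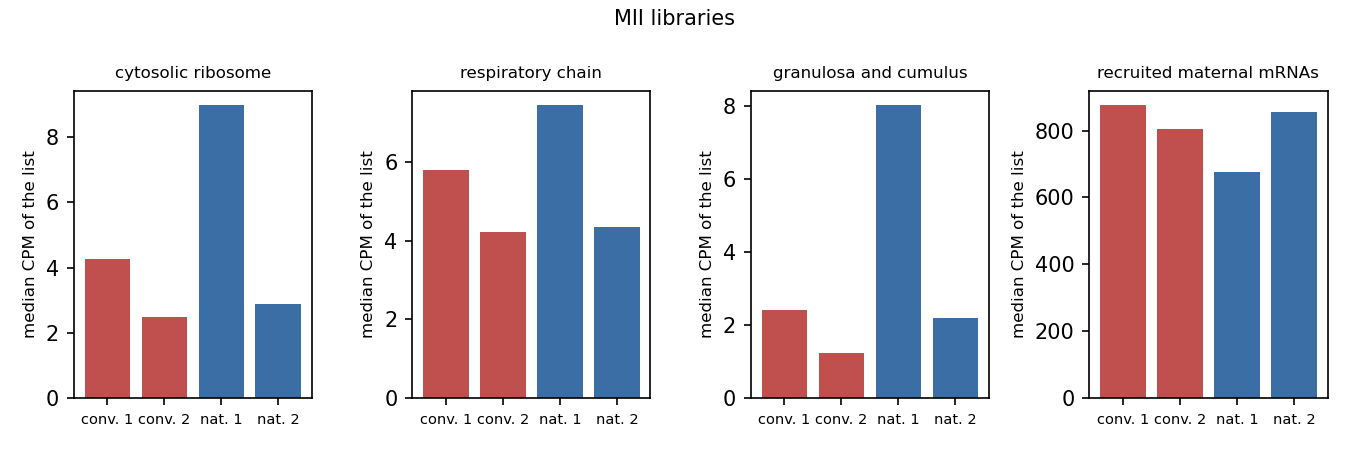
Median CPM over the tested genes of 4 lists in each of the 4 MII libraries, with 1 bar per library, sex-converted in red and native in blue. Native MII replicate 1 had the highest median of the 4 libraries for cytosolic ribosomal protein genes (8.98 CPM), respiratory chain genes (7.45 CPM) and granulosa and cumulus markers (8.02 CPM), and the lowest for recruited maternal mRNAs (675 CPM).

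Maturation in the native line changed 9741 of the 14929 tested genes, 4414 higher and 5327 lower at MII. The change is relative to the other mRNAs of the oocyte, since all libraries were scaled to a common composition. The libraries were made from polyadenylated RNA. In either line, a change in poly(A) tails therefore cannot be told apart from a change in mRNA amount. Cumulus cells were removed with a glass capillary at GV and with hyaluronidase at MII. A rise from 0 or few reads at GV, as for Spp1 and Thbs1 below, therefore cannot be told apart from somatic RNA in MII pools. Among the genes that rose most were Gtf2a1, a subunit of general transcription factor IIA, from 14.0 ± 1.11 to 1303 ± 46.1 CPM (SD, n = 2 each, log2 fold change 6.54 ± 0.241, SE), and Foxn2, a forkhead factor gene, with 5.87 ± 0.20. Khsrp, an RNA-binding splicing and decay factor, rose with a log2 fold change of 6.05, the endoplasmic reticulum retention receptor gene Kdelr2 with 5.42, Cpeb4, which directs cytoplasmic polyadenylation, with 5.30, and Lbr, the lamin B receptor, with 5.23. Among the genes that fell most were Gnl2, a GTPase of ribosome assembly, from 146.3 ± 49.5 to 1.91 ± 0.407 CPM (log2 fold change -6.24 ± 0.36, SE), and Rpf2, another ribosome assembly factor, with -6.32 ± 0.668. Meikin, a kinetochore regulator of the first meiotic division, had 3 reads at MII against 526 at GV, a ratio of 104 (95% counting interval 35.5 to 507), or 57.1 without native MII replicate 2 and at least 47.1 without replicate 1. Psmc3ip, a meiotic recombination factor, fell with a log2 fold change of -6.43, and without native MII replicate 1 it had 2 reads against 1192, a ratio of 160 (95% counting interval 44.2 to 1320). These genes had edgeR adjusted p values from 1.04e-07 to 1.16e-05. At a 2-fold change or more, 3882 genes rose and 4968 fell. Spp1, the secreted phosphoprotein osteopontin, had 0 reads at GV and 356 at MII, 303 of them in native MII replicate 1, at least 200-fold higher. The bound was 65.8 without that library and 310 without native MII replicate 2, and 88.2 and 111 without native GV replicates 1 and 2. In the sex-converted line Spp1 likewise had 0 reads at GV and 420 at MII, 313 of them in sex-converted MII replicate 1, at least 266-fold higher, with a bound of 127 and 426 without MII replicates 1 and 2 and of 146 and 120 without GV replicates 1 and 2. Thbs1 and Nupr1, which stromal and stressed cells express, had log2 fold changes of 6.62 ± 1.35 and 6.19 ± 0.926 (SE) that were 3.97 and 4.62 without native MII replicate 1 and 7.47 and 6.89 without replicate 2. Without native GV replicate 1 Thbs1 had 0 reads at GV and was at least 111-fold higher at MII. Without native GV replicate 2 its log2 fold change was 5.73, and Nupr1 had 3 reads at GV, a ratio of 136 (95% counting interval 46.1 to 660). With library totals as the only scaling, the median log2 fold change of all genes moved by -0.908 and the calls became 2488 higher and 7614 lower, 24.6% higher against 45.3% with the scaling used here.

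Maternal mRNAs that are known to be polyadenylated or translated in maturation, called recruited here, rose as a list in the native line. In libraries of polyadenylated RNA, a list defined in part by polyadenylation may rise for that reason. Its test therefore does not show a rise in mRNA amount. Of 26 tested, 22 rose and 3 fell, with a median log2 fold change of 1.98 (camera adjusted p = 6.81e-08, and adjusted p = 0.396 with an estimated correlation). Btg4, the adaptor of maternal mRNA deadenylation, rose with a log2 fold change of 3.72 ± 0.153 (SE), the decapping activator gene Dcp1a with 3.54, the meiotic inhibitor gene Fbxo43 with 3.04, Ccnb1 with 2.26 and Mos with 1.82. The 3 members that fell were the phosphatase gene Cdc25c (-4.27, or a ratio of 48.4 from 2 reads at MII without native MII replicate 1, 95% counting interval 13.3 to 401), Aurkaip1 (-3.51, or -5.24 without native MII replicate 1 and -2.82 without replicate 2) and the maintenance methyltransferase gene Dnmt1 (-1.64). Genes of mRNA decay and poly(A) control went both ways, 15 higher and 11 lower of 34 (camera adjusted p = 0.0537, and adjusted p = 0.592 with an estimated correlation). The list was not called except without native MII replicate 1 (adjusted p = 0.0473) or replicate 2 (adjusted p = 0.0227) and with the GC trend removed (adjusted p = 0.045). Cpeb4 and Btg4 led its rises, and Cnot10 (-4.85) and the scaffold Cnot1 (-3.29) of the CCR4-NOT deadenylase led its falls. Genes of oocyte identity also went both ways, 15 higher and 18 lower of 39. The apoptosis regulator gene Bcl2l10 (2.79) and Oosp1 (2.61) rose, while Figla (-4.36) and Nobox (-3.83), transcription factors of the growing oocyte, fell together with Zp3 (-1.84), Nlrp5 (-1.18) and Bmp15 (-1.16). Gdf9 rose by a log2 fold change of 1.08 and Dppa3 by 0.82. With library totals as the only scaling these were 0.17 (adjusted p = 0.233) and -0.088 (adjusted p = 0.683), so the call of Gdf9 was lost and the direction of Dppa3 turned.

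Genes of 5 housekeeping and small RNA groups fell as lists in the native line. Cytosolic ribosomal protein genes had 71 of 87 lower and 5 higher, or 74 and 6 when adjusted over the list alone, with a median log2 fold change of -2.77 (camera adjusted p = 6.23e-07, and adjusted p = 0.592 with an estimated correlation). Rpl17 fell with a log2 fold change of -4.75, or -5.34 without native MII replicate 1, while Rps27l, a p53-inducible paralog, rose with 2.03 and Rpl13a with 1.33, the latter being 0.42 (adjusted p = 0.138) with library totals as the only scaling. The many processed pseudogenes of ribosomal protein genes make single members uncertain. Without native MII replicate 1, the library with the highest ribosomal protein and granulosa medians, the list median was -4.06. Genes of the mitochondrial ribosome fell in 58 of 76 cases and rose in 5, with a median of -2.36 (adjusted p = 1.95e-07, and adjusted p = 0.455 with an estimated correlation), from Mrps22 at -5.98, or -6.74 without native MII replicate 1, to Mrpl3 at 2.11. Nuclear genes of the respiratory chain fell in 63 of 82 cases and rose in 5, with a median of -2.14 (adjusted p = 8.39e-07, and adjusted p = 0.592 with an estimated correlation). Ndufb4 fell with -4.81, and Cox6b2, the testis-type isoform of a cytochrome oxidase subunit, rose with 1.72. Proteasome genes fell in 30 of 43 cases and rose in 5, or 6 when adjusted over the list alone, with a median of -2.10 (adjusted p = 0.000275, and adjusted p = 0.592 with an estimated correlation). The ATPase subunit gene Psmc2 fell with -5.56, or -7.89 without native MII replicate 1 and -4.80 without replicate 2, and the activator gene Psme4 rose with 2.21. Genes of the piRNA and siRNA pathways fell in 18 of 25 cases and rose in 3, or 4 when adjusted over the list alone, with a median of -1.51 (adjusted p = 0.0118, and adjusted p = 0.396 with an estimated correlation). Mov10, an RNA helicase, fell with -4.04 and Ago3 rose with 3.08. All 5 lists also fell by fry, but fry called 18 of the 24 tested lists in this line, so its calls do not set these 5 apart.

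**Figure D3:**
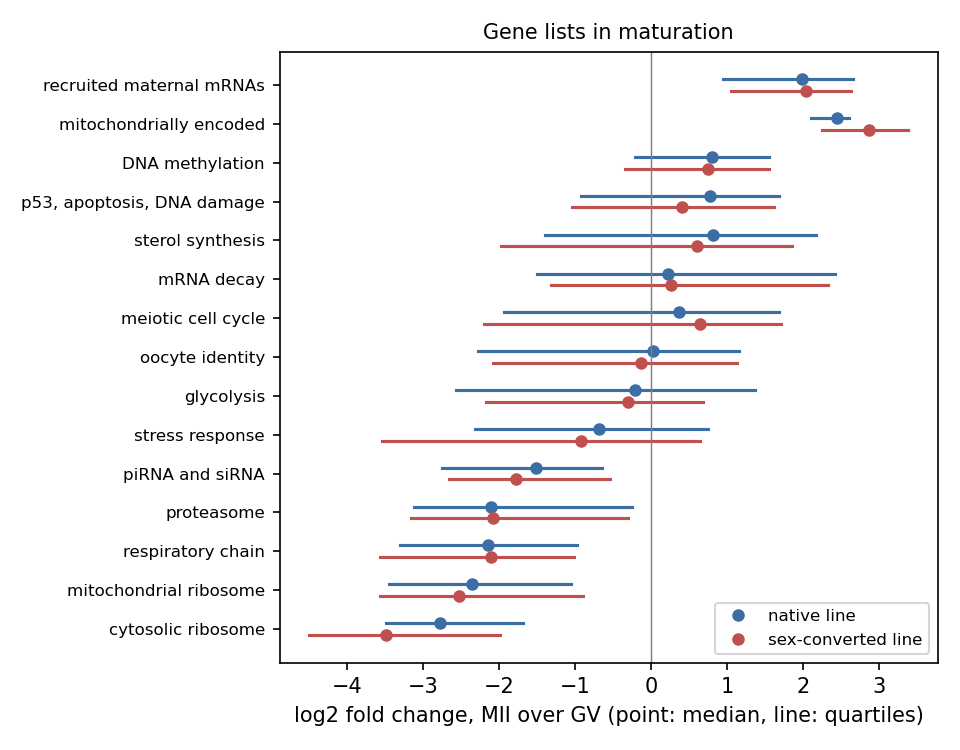
Log2 fold change of MII over GV for 15 gene lists, with the median as a point and the quartiles as a line, native line in blue and sex-converted line in red, and genes with 0 reads in one group set at their bound. Recruited maternal mRNAs had medians of 1.98 and 2.04, and cytosolic ribosomal protein genes had -2.77 and -3.49.

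Genes encoded by mitochondrial DNA rose while nuclear genes of the same complexes fell. In the native line 8 of 9 rose and 0 fell, or 9 when adjusted over the list alone. The list had a median log2 fold change of 2.44 and was not called by camera (adjusted p = 0.0629, and adjusted p = 0.709 with an estimated correlation). It was called with library totals as the only scaling (adjusted p = 0.0106), with the GC trend removed (0.0306), and without native GV replicate 1 (median 3.72, 0.00172), MII replicate 1 (2.32, 0.0495) or MII replicate 2 (2.63, 0.0227), and its median was 1.77 without native GV replicate 2 (0.105). In the sex-converted line 9 of 9 rose, with a median of 2.86 (camera adjusted p = 0.0384, and adjusted p = 0.767 with an estimated correlation), or 3.90 without sex-converted GV replicate 2 (adjusted p = 0.000501). The cytochrome b gene mt-Cytb rose with log2 fold changes of 3.49 ± 0.551 and 3.56 ± 0.553 (SE) in the native and sex-converted lines. Its GV level was 222 and 78.9 CPM in the native libraries and 74.6 and 250 CPM in the sex-converted ones. Without native GV replicate 1 its log2 fold change was 4.44, and without sex-converted GV replicates 1 and 2 it was 2.95 and 4.72.

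With all libraries and TMM scaling the other lists were called by camera in neither line. With an estimated correlation camera called 0 lists in either line, and DNA methylation genes had an adjusted p of 0.455 in the native line. DNA methylation genes were called in the native line without native MII replicate 2 (adjusted p = 0.0364) and with the GC trend removed (adjusted p = 0.0413). Among meiotic cell cycle genes 24 of 49 rose and 19 fell in each line, with the cohesin protector gene Sgo2a at 2.40 in the native and 3.01 in the sex-converted line and the kinase gene Cdk1 at -4.82 and -4.93. Without native MII replicates 1 and 2 Cdk1 had -6.88 and -4.08, and without sex-converted MII replicates 1 and 2 it had -6.44 and -4.17. Of 29 DNA methylation and chromatin genes, 15 rose in each line and 6 fell in the native and 7 in the sex-converted line. The methylcytosine dioxygenase gene Tet3 rose with 4.31 and 4.35, and Zfp57, which protects imprints, fell with -2.51 and -2.55. Of 35 imprinted genes 13 and 12 rose and 8 and 7 fell, with Zdbf2 at 3.86 and 3.47, and Cdkn1c at 2 MII reads in each line against 346 and 360 at GV, ratios of 103 and 94.8 (95% counting intervals 28.2 to 852 and 26.1 to 786). Without MII replicate 2 of the line these ratios were 56.3 and 44.1, and without MII replicate 1, where 0 reads were left, at least 31 and 33.8. Of 28 genes of p53, apoptosis and DNA damage 13 and 12 rose and 8 fell in each line, with Trp53inp1 at 4.89 and 4.90 and the p53 inhibitor gene Mdm2 at 2.55 and 2.56, while Bax fell with -2.02 and -2.22, the latter being -3.22 without sex-converted MII replicate 2. Of 29 stress genes 7 and 3 rose and 11 and 15 fell, with the chaperone genes Hspa8 at -5.09 and -5.33, or -5.68 and -5.98 without MII replicate 1 of the line, and Hsph1 at -4.86 and -4.81. Of 22 genes of sterol synthesis 11 and 8 rose and 5 and 8 fell, with Hmgcs1 at 2.57 and 2.76 and Fdft1 at -3.62 and -3.54, the latter being -4.19 without sex-converted MII replicate 1. Of 19 glycolysis genes 5 and 4 rose and 6 fell in each line, with Hk2 at 3.93, or 4.71 without native GV replicate 2, and 4.00 and Gpi1 at -3.48 and -3.53. Of 306 zinc finger genes 62 and 67 rose and 126 and 122 fell, with Zfp606 at 4.13 in both lines. With library totals as the only scaling the list medians of DNA methylation, p53 and sterol genes lay below 0 in both lines. That scaling moved the median of all genes by -0.908 in the native and -0.932 in the sex-converted line, so the shift is not particular to these lists.

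Pluripotency and germ cell genes rose in 8 of 16 cases in each line and fell in 4 in the native and 5 in the sex-converted line. Lin28a rose with 3.48 and 3.19, Sall4 with 3.10 and 3.01, and Dppa2 fell with -4.31, or -3.59 without native GV replicate 1, and -4.47, while Dppa4 had 0 reads in sex-converted MII oocytes against 456 at GV, at least 80.1-fold lower, or at least 42.8-fold and 37.2-fold without sex-converted MII replicates 1 and 2. Of 12 testis genes 2 and 1 rose and 5 fell in each line, led in the native line by the helicase gene Ddx25 at -4.54, or -6.26 without native MII replicate 1 and -3.87 without replicate 2. In the sex-converted line the protamine gene Prm2 led, with 2 reads at MII against 118 at GV, a ratio of 31.1 (95% counting interval 8.42 to 260), or 20.5 without sex-converted GV replicate 2, 14.4 without MII replicate 2 and at least 11.1 without MII replicate 1, before Ddx25 at -3.95. Of 6 genes of the 2-cell embryo, a family with near-identical copies whose members are uncertain, 0 rose and 2 and 3 fell. Of 12 X inactivation centre and escape genes 5 rose in each line and 4 and 5 fell, with Ddx3x at 2.58 and 2.57, Kdm6a at 2.79 and 2.99 and Eif2s3x at -2.72 and -3.21, the latter being -3.80 without sex-converted MII replicate 1. Xist was called higher at MII in both lines, with 22 reads against 0 in the sex-converted line, at least 13.9-fold, and 90 against 2 in the native line, a ratio of 75.7 (95% counting interval 20.4 to 635). Cumulus cells were removed in different ways at GV and at MII. Higher Xist in the oocytes thus cannot be told apart from somatic RNA in the MII pools. Without native MII replicate 1 the native call was lost (7 reads against 2, a ratio of 13, 95% counting interval 2.48 to 129, adjusted p = 0.111), while the ratio was 127 without MII replicate 2 and 42.3 without GV replicate 2, and the fold was at least 22.3 without GV replicate 1. Without sex-converted MII replicate 1 the sex-converted call was lost (3 reads against 0, adjusted p = 0.119), while the bound was 25.9 without MII replicate 2 and 7.66 and 6.26 without GV replicates 1 and 2. The 1 tested Y-linked gene, Kdm5d, was at least 14.4-fold lower at MII in the sex-converted line and lower by a ratio of 16.3 (95% counting interval 4.31 to 138) in the native line. With a library left out the sex-converted bound was lowest without MII replicate 2 (6.69), and the native ratio was 8.95 without MII replicate 2 with a bound of 4.92 without MII replicate 1.

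Granulosa and stromal markers rose more often than they fell in MII pools, without a camera call in either line with all libraries and TMM scaling. Since cumulus cells were removed in different ways at GV and at MII, these rises cannot be told apart from somatic RNA in the pools. Granulosa and cumulus markers rose in 7 of 15 cases and fell in 1 in the native line, and rose in 5 and fell in 1 in the sex-converted line. Cyp19a1, the aromatase gene, which was already at 12.4 to 19.4 CPM in the GV pools, rose with a log2 fold change of 1.93 in the sex-converted line. Stromal markers rose in 4 of 12 cases in each line and fell in 1 and 2. Acta2, smooth muscle actin, had 0 reads at GV and was at least 8.98-fold higher in the native and 27.8-fold higher in the sex-converted line. The native bound was 13.6 without MII replicate 1, 5.12 without MII replicate 2, where the call was lost (adjusted p = 0.0506), and 3.97 and 5.01 without GV replicates 1 and 2. The sex-converted bound was 10.6 and 47.6 without MII replicates 1 and 2 and 15.3 and 12.5 without GV replicates 1 and 2. Vcan, a matrix proteoglycan of the cumulus, was at a native log2 fold change of 4.17, and its call was lost without native MII replicate 1 (1.88, adjusted p = 0.204), while it had 4.98 without replicate 2 and a ratio of 34.6 (95% counting interval 9.31 to 290) from 2 reads at GV without native GV replicate 1. Without native MII replicate 1 the native calls of the immediate early genes Jun (adjusted p = 0.0921) and Fos (adjusted p = 0.791) were lost too, and that of Fos also without native GV replicate 2 (adjusted p = 0.0879) and with library totals as the only scaling (adjusted p = 0.0569). Of 5 endothelial and blood markers 1 and 2 rose and 2 fell in each line. With an estimated correlation the granulosa list had a camera adjusted p of 0.592 in the native line. Camera called none of these 3 lists, except the granulosa list in the native line when library totals were the only scaling (adjusted p = 0.0358) and without native MII replicate 2 (adjusted p = 0.0121).

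Maturation in the sex-converted line changed 9782 genes, 4374 higher and 5408 lower. Gtf2a1 rose from 16.0 ± 4.44 to 1344 ± 55.2 CPM (SD, n = 2 each, log2 fold change 6.39 ± 0.239, SE), Rhobtb3 with 5.65, or 6.39 without sex-converted GV replicate 2, Foxn2 with 5.37, Khsrp with 5.35, Kdelr2 with 5.23, Fubp3 with 4.98 and Cpeb4 with 4.91. Nop56, a core protein of small nucleolar ribonucleoproteins, fell from 66.2 ± 1.28 to 0.252 ± 0.0469 CPM (log2 fold change -7.97 ± 0.584, SE), Polrmt, the mitochondrial RNA polymerase, fell with -7.36 ± 0.394 and the transcription factor gene Irf1 with -7.15, or -7.77 without sex-converted MII replicate 1. The ribosomal RNA processing genes Ddx49 and Wdr12 had 3 and 2 reads at MII, with GV to MII ratios of 216 (95% counting interval 73.9 to 1050) and 170 (46.9 to 1410), the former being 101 without sex-converted MII replicate 2 and at least 116 without replicate 1. These genes had edgeR adjusted p values from 1.26e-07 to 4.88e-06. At a 2-fold change or more, 3817 genes rose and 5040 fell. With library totals as the only scaling the median log2 fold change of all genes moved by -0.932 and the calls became 2372 higher and 7785 lower, 23.4% higher against 44.7%.

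The same lists moved in the sex-converted line, with the same limit for recruited maternal mRNAs, whose definition includes polyadenylation. Recruited maternal mRNAs rose in 23 of 26 cases and fell in 3, with a median log2 fold change of 2.04 (camera adjusted p = 2.05e-08, and adjusted p = 0.186 with an estimated correlation). Btg4 rose with 3.61, Dcp1a with 3.33, Ccnb1 with 2.20 and Mos with 1.86, and Cdc25c had 2 reads at MII against 377 at GV, a ratio of 99.3 (95% counting interval 27.3 to 823). Ribosomal protein genes fell in 73 of 87 cases and rose in 6, with a median of -3.59, or -3.49 with genes at 0 reads set at their bound (adjusted p = 2.05e-08, and adjusted p = 0.671 with an estimated correlation). Genes of the mitochondrial ribosome fell in 58 of 76 cases and rose in 6, with a median of -2.52 (adjusted p = 1.4e-07, and adjusted p = 0.671 with an estimated correlation). Respiratory chain genes fell in 62 of 82 cases and rose in 7, or 63 and 7 when adjusted over the list alone, with a median of -2.10 (adjusted p = 4.39e-07, and adjusted p = 0.671 with an estimated correlation). Proteasome genes fell in 28 of 43 cases and rose in 5, or 29 and 6 when adjusted over the list alone, with a median of -2.08 (adjusted p = 0.000471, and adjusted p = 0.671 with an estimated correlation). Genes of the piRNA and siRNA pathways fell in 16 of 25 cases and rose in 4, or 17 and 4 when adjusted over the list alone, with a median of -1.78 (adjusted p = 0.0149, and adjusted p = 0.507 with an estimated correlation). Oocyte identity genes rose in 15 of 39 cases and fell in 19, with Figla at -3.97, or -3.14 without sex-converted MII replicate 2 and a ratio of 58.8 (95% counting interval 20 to 286) from 3 reads at MII without replicate 1, Nobox at -3.86, Zp3 at -2.07, Nlrp5 at -0.96, Bcl2l10 at 2.74 and Gdf9 at 1.02. Genes of mRNA decay rose in 14 of 34 cases and fell in 13, and their list was called only without sex-converted MII replicate 2 (adjusted p = 0.0344). Bmp15 fell with -0.76, and its call was lost without sex-converted GV replicate 2 (-0.56, adjusted p = 0.112) or MII replicate 2 (-0.44, adjusted p = 0.166). The calls of Gdf9 (adjusted p = 0.551) and Rpl13a (adjusted p = 0.412) were lost with library totals as the only scaling.

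The change in maturation was shared by the lines to a large degree, and 0 genes were called as differing between them. In both lines 4017 genes rose and 4773 fell, where independent lists of these sizes would share 1293 and 1930, and 0 genes were called in opposite directions. The lines share no libraries. Across genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.907 and a slope of 0.919. The test of the line by stage interaction in edgeR gave 0 calls, with 329 genes at an unadjusted p under 0.05, and DESeq2 also gave 0. The log2 difference of sex-converted minus native was -0.11 for Btg4 (SE 0.195), -0.062 for Gdf9 (SE 0.179), -0.23 for Zp3 (SE 0.354) and 0.041 for Tet3 (SE 0.364). Of 24 lists camera called 1 of the interaction, cytosolic ribosomal protein genes, with a median of -0.52 (adjusted p = 0.000128, and adjusted p = 0.941 with an estimated correlation). It turned to 0.37 (adjusted p = 0.0311) without native MII replicate 1 and was lost without sex-converted MII replicate 2 (-0.25, adjusted p = 0.284). The line differences at GV and MII, which also share no libraries, had a Pearson correlation of 0.0886 across genes, and the 2 genes called at both stages were Parp8 and Gm14820.

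**Figure D4:**
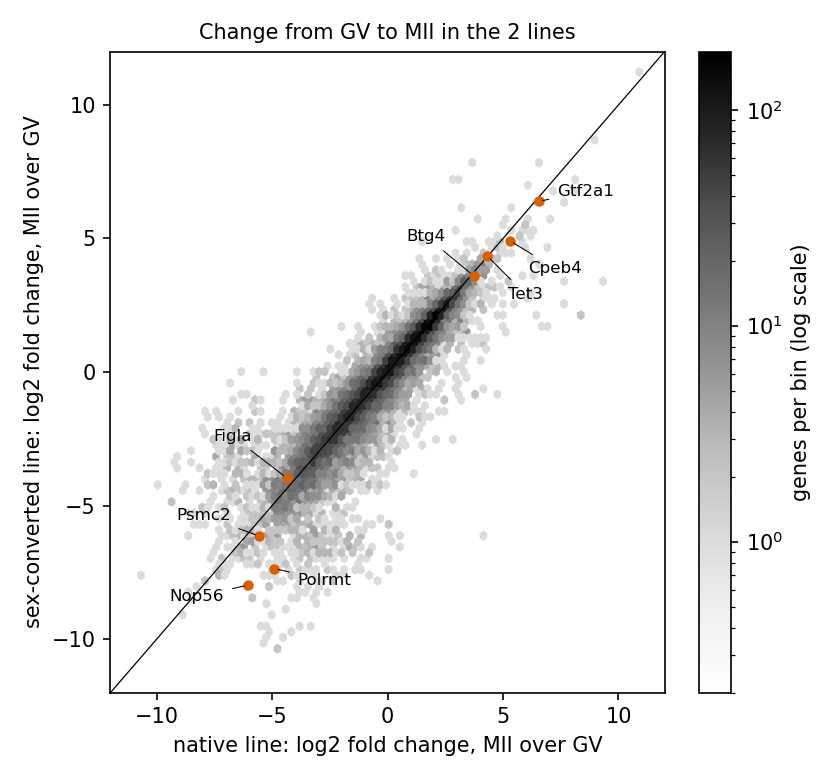
Log2 fold change of MII over GV in the native line (horizontal axis) and in the sex-converted line (vertical axis) for the 14929 tested genes, shaded by the number of genes per bin on a log scale, with the line of equal change and 8 named genes in orange. The correlation was 0.907, and genes such as Nop56 and Polrmt that lay below the line of equal change had few reads at MII. Polrmt had 2 and 2 reads in the sex-converted and 14 and 10 in the native MII libraries, and Nop56 had 2 and 3 and 19 and 2.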

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

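The tests of somatic RNA and of immature oocytes, and the removal of the GC trend, were chosen after the result was seen. The median log2 difference of cytosolic ribosomal protein genes between the lines in their change from GV to MII was -0.516, and camera called the interaction (adjusted p = 0.000128, and 0.941 with an estimated correlation; fry 0.983). The difference arose at MII, where the 87 genes had a median of -0.64 in sex-converted over native oocytes, with 0 of them called by edgeR.

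The tables argue against GC content as the whole cause of the lower ribosomal protein genes, since the median at MII was -0.587 (adjusted p = 3.97e-09) with the GC trend removed. They also argue against immature oocytes of the GV stage in the pool of native MII replicate 1 as the whole cause, since such oocytes would add a like percentage of the native GV level to each gene. The median excess of that library over native MII replicate 2 was 3.3% of the native GV level (quartiles 1.69 to 5.31) for 175 genes that fell at least 32-fold in the sex-converted line, and 11.5% (quartiles 6.81 to 19.5) for the ribosomal protein genes. Oocytes that had lost only part of these mRNAs were not tested, and this stays open. The 175 genes were at a median of 5.26% of the native GV level in native MII replicate 1 and 1.7% in native MII replicate 2. They were at 2.59% and 1.38% in sex-converted MII replicates 1 and 2. For ribosomal protein genes these medians were 20.8% and 6.03%, and 10.6% and 5.44%, so both sets were highest in native MII replicate 1. RNA of somatic cells in native MII replicate 1 is a candidate explanation, as without that library the median at MII was 0.253 (adjusted p = 0.396), the interaction turned to 0.375 (adjusted p = 0.0311), and the granulosa and cumulus markers there had a median of 8.02 CPM against 1.24 to 2.41 CPM in the other MII libraries. Of the markers with reads at MII, 9 of 14 granulosa and cumulus, 7 of 12 stromal and 2 of 5 endothelial and blood ones were highest in that library, so not all markers follow. The stromal median was 1.34 CPM there against 1.45 CPM in native MII replicate 2, and Acta2 (0.477 CPM), Has2 (4.58 CPM) and Kitl (21.2 CPM) were lower there than in the other MII libraries. Leaving a library out does not show what sets it apart, cumulus cells were stripped with hyaluronidase and MII oocytes picked by their polar body, and 8 of the 15 tested markers were at 1 CPM or more at GV, among them the most abundant, Serpine2, at 969 and 937 CPM in sex-converted and native MII oocytes. A difference between the lines themselves stays open and untested beyond this, as only native MII replicate 2 then stands for its group.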

How the results depend on the processing

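Removal of the GC trend, the GV covariate and the looser threshold for line differences were chosen after the data were seen. The counts of genes called in maturation stayed within 1.5 times under all alternatives run, from 8405 to 8888 in the native and 8001 to 8741 in the sex-converted line with a library left out. Chromosomes had 0 calls under all alternatives run. For line differences at GV, 2 genes became 13 with no low-count filter, 1 at an adjusted p under 0.01, 1 with only the 4 libraries compared and 1 to 3 with a library left out. At MII, 2 genes became 34 with no filter, 0 with library totals, 0 with at least 50 reads, 0 at an adjusted p under 0.01, 1 with only the 4 libraries compared and 0 to 3 with a library left out. The overlap of line differences was then 0 with library totals and 0 with at least 50 reads, and 9 at an unadjusted p under 0.01 in both. The interaction gave 3 genes with no filter and 0 otherwise. Without the filter more genes with few reads were tested, and fitting 4 libraries leaves fewer degrees of freedom, while the cause of the other changes was not tested.

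The replicate numbers were not shown to pair libraries. For this, the deviation of each library's log CPM from its group mean was compared between same-numbered libraries of the lines. Across genes these deviations had correlations of -0.443 at GV and 0.171 at MII. With the replicate block MII line calls were 0 and 1 list was called at GV. It was the 2-cell list, and maturation calls were 9288 and 9350. A covariate crossing the GV numbers gave 2 and 2 line calls, 10334 and 10430 maturation calls and 0 for the interaction.

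Gene lists called for the line at GV were 0, but 1 with RLE factors and 1 to 5 with a library left out. At MII they were 2, but 0 with an estimated correlation, 0 with fry and 0 to 7 with a library left out. In the native line they were 6, but 0 with an estimated correlation, 18 with fry and 6 to 10 with a library left out. In the sex-converted line they were 7, but 0 with an estimated correlation, 17 with fry and 7 to 8 with a library left out. For the interaction they were 1, but 0 with an estimated correlation, 0 with fry and 1 to 5 with a library left out. With a library left out, the ribosomal protein median at MII ran from -1.16 to 0.253, that of the respiratory chain from -0.389 to 0.196 and that of the ribosomal protein interaction from -0.979 to 0.375, all turning without native MII replicate 1.

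X to autosome ratios, in sex-converted and native oocytes, were 0.558 and 0.601 at GV and 0.906 and 0.878 at MII with no filter, and 0.875 and 0.848 at GV and 0.993 and 0.907 at MII with at least 50 reads. The order of the lines thus turned at MII with no filter and at both stages with at least 50 reads. Not divided by length they were 0.584 and 0.591 at GV and 0.804 and 0.809 at MII. Of named genes, Dppa3 turned to -0.0881 in the native line with library totals. Of the 96 and 87 genes tracked in maturation, 9 and 9 lost their call under at least 1 alternative. Depth limits genes under 3 reads per group, for which only bounds or counting intervals hold.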

Other observations

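All tests of Parp8 and Gm14820 and that of maturation in the GV libraries were chosen after the result was seen, as was the looser threshold, and GC removal was added after the data were seen. At an unadjusted p under 0.01 in both line comparisons there were 9 genes, 3 higher and 6 lower in the sex-converted line at both stages and 0 in opposite directions, where independent lists would share 0.0818 and 0.0427. Besides Parp8 and Gm14820 these were named after their values were seen. Gm47913 lies near Parp8, and B930036N10Rik, an antisense gene of chromosome 1, had log2 fold changes of 1.31 at GV and 1.37 at MII. Dync1i1, an intermediate chain of cytoplasmic dynein, had -1.12 and -1.67, and the long non-coding RNA gene Gm42953 had -2.20 and -2.27. The other 3 are pseudogenes with close copies, whose reads are uncertain. Gm14576 on the X chromosome had 0 reads in all 4 sex-converted libraries and 16 to 20 in the native ones, Magea7-ps on the X chromosome had 3 to 7 and 22 to 49, and Mid1-ps1 on the Y chromosome had 0 to 1 and 7 to 37. The reads of Mid1-ps1 in native XX oocytes were not analysed further. With the low-count filter none apart from Parp8 and Gm14820 passed the adjusted threshold at either stage in edgeR. Without it Gm47913, Gm14576 and Mid1-ps1 passed at both stages and Magea7-ps at MII.

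The differences in Parp8 and Gm14820 between the lines held with the GC trend removed, where the smallest of the 4 absolute log2 fold changes was 3.48 and the adjusted p values were 0.0183 or less. A loss of the region around Gm14820 is argued against by its 28 other tested neighbours within 1 Mb, whose log2 fold changes at GV had a median of -0.0524 (median absolute deviation 0.22) and a lowest value of -0.499. At MII their median was -0.122, but single neighbours ran from -4.57 to 1.21, so the argument rests on the GV values. A gain of a segment that holds Parp8 and Gm47913 cannot be told apart from another regulation. The 5 other tested neighbours of Parp8 had a median of -0.0763 (median absolute deviation 0.146), but Gm47913 among them was higher at GV in the sex-converted line. Against the floor of 3 reads it was 14.7-fold higher, or 6.48-fold without native GV replicate 1 and 8.18-fold without replicate 2. A sequence difference on the X chromosome cannot be told apart from another regulation, since the reads were not analysed here and the labels give both lines the same mixed strain. Of the 8 genes other than Gm14820, 2 lie there against 3.52% of tested genes (exact one-sided p = 0.0301), but these are pseudogenes with uncertain reads that had been seen before the test was set up, so this decides nothing. With 1 line of each kind, a difference made by sex conversion and a difference between any 2 lines stay open as untested.

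The 4 GV libraries split more across the lines than between them. Sex-converted replicate 1 and native replicate 2 against the other 2 differed in 2310 of 14361 genes in edgeR, 1181 higher and 1129 lower, where the split by line gave 1 and that by number 0, and this points to a structure of the samples other than the line. A difference in library size is argued against by 2249 calls after thinning to the smallest total, and oocytes of one pair being further on in maturation by a Spearman correlation of -0.00276 across genes with the change from GV to MII. GC content may account for part, since fold changes of the split correlated with it across genes (Spearman 0.445), yet 1232 calls were left with the trend removed, so GC and another difference between preparations cannot be told apart. Beyond maturation no biological explanation was tested, as no group of the design follows this split.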
